A study of Mus musculus with 9 samples.

How the data were processed

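The material was poly(A)+ RNA from 9 libraries of mouse embryonic stem cells, 4 wild-type and 5 carrying a Gzf1 knockout. Per the labels' protocols, the cells grew on irradiated fibroblast feeders in serum medium with LIF and the feeders were removed before harvest. Libraries were made with MARS-seq2.0, a method that tags and counts the 3' ends of polyadenylated transcripts. A 3' tag lying outside an edited part of a gene need not report the edit, so the Gzf1 level is not a direct check of the deletion, and the position of the edit is not given in the sources used here.

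The authors deposited one table of raw counts per gene symbol, with whole numbers and a different total for each library. STAR, DESeq2 and the genome build mm10 are named in the submitters' processing notes, without versions or roles. The counter, the annotation, the handling of strand and whether reads or unique molecular identifiers were counted are not given in the sources used here. The deposited counts fill 30324 rows. Of these, 92 are synthetic spike-in rows, which were left out of library sizes and tests because 1 of them held a count. A further 9860 gene rows had no count in any library, and 1858 rows (6.15%) name several overlapping symbols merged into 1 value, so that transcripts in such a row cannot be separated. Whether a gene and an overlapping or antisense transcript shared reads cannot be read from the counts.

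Library totals ranged from 2568490 to 7072697 counts. The 4 libraries of run2, all from the RGM cell line, held 2568490 to 3704162 counts, and the 5 libraries of run1 held 4872127 to 7072697. A count of 3, taken as the floor, corresponded to between 0.412 and 1.18 CPM (counts scaled to library size) depending on the library. The floor covers counting error only, since the counts may not be independent molecules. No pair of libraries of the same genotype and run agreed within sampling noise. The chi-square statistic per degree of freedom was 2.53 and 3.16 for the pairs of run2 and 15.1 to 26.0 for the pairs within a genotype in run1, so each library was counted as 1 replicate. The labels do not say whether libraries came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical.

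Genotype, cell line and run were taken from the labels. Wild-type replicates 1 and 2 and knockout replicates 1 and 2 are RGM cells of run2. Wild-type replicate 3 and knockout replicates 3, 4 and 5 are V6.5 cells of run1, and wild-type replicate 4 is a Cas9-GFP line of run1. Run and cell line therefore cannot be separated. Genes were kept with filterByExpr (minimum count 10, genotype as the group), which left 12645 genes. Counts were scaled with TMM factors and tested in edgeR 4.0.16 (R 4.3.3) with the robust quasi-likelihood F test, with run and genotype as terms, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Every p and adjusted p of a gene given without another tool's name comes from edgeR. The standard error (SE) of a log2 fold change is the one implied by the F statistic, the absolute log2 fold change divided by the square root of F. CPM values use the TMM-scaled library sizes. The knockout effect within each run and its difference between runs came from contrasts of a fit with 4 groups (genotype by run), in which all libraries shared the estimate of spread.

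Gene lists fixed before the data were examined were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with p-values adjusted over the 21 lists that had at least 3 tested members. Estimated inter-gene correlations and fry were the alternatives. The lists of 2-cell-like genes (1 tested member) and of genes of the mitochondrial genome (0 rows) were not tested, and a list of Xist, Tsix and Y-linked genes served only for description. The genes named in the text were chosen by a rule set before the data were examined. The rule took Gzf1, the tested members of the Dlk1-Dio3 list, passing members of the list of methylation and imprint factors, and the 10 largest rises and 10 largest falls past the threshold with the same sign in both runs. It also took the 3 genes with the smallest adjusted p of the difference between runs if past the threshold, and up to 4 members of each list (those past the threshold first, then the most highly expressed). Genes named outside this rule are said to have been chosen after their values were seen. Gene positions are from the GENCODE M21 annotation of GRCm38, the build also called mm10; 12070 of the 12645 tested rows (95.5%) held a symbol of that annotation.

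The analysis was tested on simulated data before the real counts, drawn from the means, dispersions and library sizes of these libraries. For the comparison of all libraries (12422 simulated genes), 57% of genes changed 2-fold and 93% of genes changed 4-fold were recovered, and 7.98% of the 163 calls were unchanged genes. For the contrast within run2 the shares were 19% and 73%, and within run1 31% and 83%. For the difference between runs (12409 simulated genes) they were 2% and 51%. The simulation gave both runs the same dispersions, while in the data the pairs of run1 differed more than those of run2. The higher shares for run1 therefore need not hold for the real libraries. The simulation also held many changed genes, with 163 calls against 4 in the data, which makes the adjusted threshold easier to reach. The recovered shares of every comparison therefore need not hold for the real libraries. In the simulation for gene lists, 100% of shifted lists and 3.5% of random lists had a p under 0.05. Genes were drawn independently of each other there, while members of real lists vary together, with an estimated correlation of 0.59 for glycolysis and hypoxia genes. The share for random lists therefore does not carry over to the real lists. Every member of a shifted list was raised by the same amount, larger than the median change of any real list except the Dlk1-Dio3 cluster. The share for shifted lists therefore does not carry over either.

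Alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, a minimum count of 30, no run term, cell line in place of run, the replicate number as a block, no robust estimation, a threshold of 0.1, a minimum fold change of 1.5 (glmTreat), each run's libraries alone and each library left out in turn. Added after seeing the data were DESeq2 without the low-count filter, limma voom with a weight for each library, an exact permutation of genotype within runs, and a fit without the replicate 4 library of either genotype. A further result, for 1 gene, was left out and is not reported here. Plots were drawn with matplotlib 3.10.9.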

Results

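Transcript levels were measured by 3' counting in 9 libraries of mouse embryonic stem cells, 4 of wild-type and 5 of Gzf1-knockout cells. Gzf1 encodes a zinc finger protein, and the title of the series places it, together with the imprint-protecting factor Zfp57, at the imprinted Dlk1-Dio3 cluster. The comparison therefore asks which genes change when Gzf1 is lost and whether genes of that cluster are among them. Totals were 2568490 to 3704162 counts in run2 (RGM cells, 2 wild-type and 2 knockout libraries) and 4872127 to 7072697 in run1 (2 wild-type and 3 knockout libraries, V6.5 cells except for wild-type replicate 4, a Cas9-GFP line).

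The libraries separated first by run. Principal component 1 held 64.8% of the variance and parted the 4 libraries of run2 from the 5 of run1, and component 2 (11.2%) spread the run1 libraries without parting the genotypes. Between the wild-type libraries of the runs 3081 genes differed, 1524 higher and 1557 lower in run2. Zfp42, which encodes a zinc finger protein of pluripotent cells, was higher in run2 by a log2 fold change of 3.49 (SE 0.19, adjusted p = 8.6e-07), and Tcf15, which encodes a basic helix-loop-helix transcription factor, was lower by a log2 fold change of -2.92 (SE 0.23, adjusted p = 1.9e-05). Both were chosen after their values were seen. As a list, core pluripotency factors were lower in run2 (median log2 difference -0.76, camera, adjusted p = 0.0033, and 0.26 with an estimated correlation), and naive markers had a median of -0.38 (adjusted p = 0.69). Fibroblast markers of feeder cells were higher in run2 (median 1.25, adjusted p = 5.6e-10, and 0.32 with an estimated correlation). Run and cell line coincide, so these differences cannot be assigned to either.

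**Figure D1:**
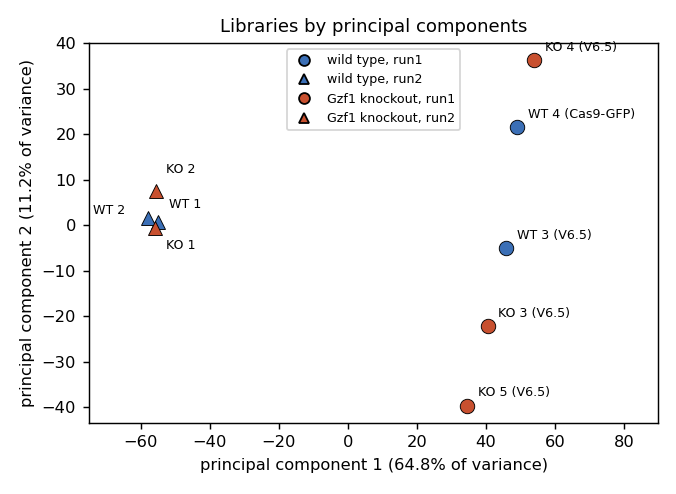
Principal components 1 (64.8% of the variance, horizontal) and 2 (11.2%, vertical) of the 9 libraries, in arbitrary units of log2 expression. Colours mark wild type (WT) and Gzf1 knockout (KO), symbols mark the run, and numbers are replicates. The run2 libraries lie together at the left and the run1 libraries spread along component 2.

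Gzf1 (chromosome 2, 148681023 to 148692949, mm10) was measured at 28.6 and 30 CPM in wild-type replicates 1 and 2, 8.11 in replicate 3 and 18.7 in replicate 4. The knockout libraries had 5.45, 14.2, 1.66, 9.40 and 5.24 CPM in replicates 1 to 5. The mean was 21.3 ± 10.2 CPM (SD, n = 4) in wild-type and 7.19 ± 4.78 CPM (SD, n = 5) in knockout libraries, a log2 fold change of -1.45 (SE 0.42). Within run2 the log2 fold change was -1.60 (SE 0.66) and within run1 -1.33 (SE 0.58). In run2 both knockout libraries lay below both wild-type libraries, while in run1 knockout replicate 4 lay above wild-type replicate 3. Adjusted over all tested genes the difference did not pass the threshold (unadjusted p = 0.0048, adjusted p = 0.9998). The call was sensitive to the model, since without the low-count filter the adjusted p was 5.0e-05. A count of 3' ends need not fall to 0 after an edit elsewhere in the gene.

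In all 9 libraries together 4 genes changed in the knockout, 0 higher and 4 lower. Hectd3, which encodes an E3 ubiquitin ligase, fell from 25.3 ± 1.45 CPM (SD, n = 4) to 4.40 ± 1.11 CPM (SD, n = 5), 5.62-fold lower (log2 fold change -2.49, SE 0.23, adjusted p = 0.00032). Cd320, the cell surface receptor for vitamin B12 bound to transcobalamin, fell from 62.6 ± 7.11 to 23.3 ± 3.58 CPM, 2.72-fold lower (log2 fold change -1.44, SE 0.15, adjusted p = 0.00077). Dnajb12, a membrane co-chaperone of the endoplasmic reticulum, fell from 19.1 ± 5.64 to 6.97 ± 2.30 CPM (log2 fold change -1.38, SE 0.21, adjusted p = 0.047). Rbmxl1, an RNA-binding protein gene derived from Rbmx by retrotransposition, fell from 94.3 ± 12.4 to 42.9 ± 14.3 CPM (log2 fold change -1.18, SE 0.18, adjusted p = 0.047). For each of the 4 genes all 5 knockout libraries lay below all 4 wild-type libraries, a separation that goes with their having been called by the same contrast.

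The fall of these genes had a similar size in either run. Hectd3 had a log2 fold change of -2.46 (SE 0.39) in run2 and -2.52 (SE 0.31) in run1. For Cd320 the values were -1.37 (SE 0.25) and -1.50 (SE 0.20), for Dnajb12 -1.35 (SE 0.34) and -1.40 (SE 0.29), and for Rbmxl1 -1.26 (SE 0.30) and -1.12 (SE 0.25). Unadjusted p-values of the difference between runs were 0.91, 0.69, 0.90 and 0.71 in the same order. The 4 genes were called by a fit to both runs, which favours genes that change alike in each, so this likeness is not independent evidence. The genes lie on different chromosomes, Hectd3 at 116995317 to 117005277 on chromosome 4, Cd320 at 33843091 to 33849774 on chromosome 17, Dnajb12 at 59879556 to 59899302 on chromosome 10 and Rbmxl1 at 78505269 to 78508898 on chromosome 8 (mm10). An annotated antisense transcript overlaps Hectd3, and Rbmxl1 has related copies, so reads of either may be shared. Rbmx itself had a log2 fold change of 0.28 (SE 0.26, adjusted p = 0.9998) and Rbmxl2 one of 0.40 (SE 0.13, adjusted p = 0.9998), both named after the call of Rbmxl1 was seen.

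**Figure D2:**
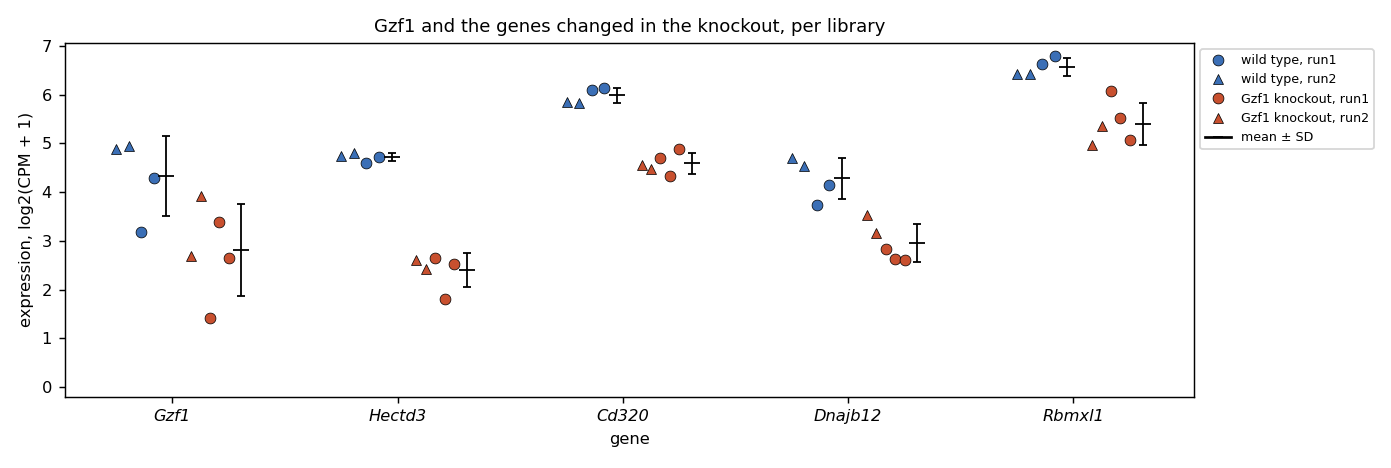
Expression of Gzf1 and of the 4 genes changed in the knockout as log2(CPM + 1) (vertical) for each gene (horizontal). Each point is a library, coloured by genotype and shaped by run, and black marks give mean ± SD of 4 wild-type and 5 knockout libraries. Hectd3, Cd320, Dnajb12 and Rbmxl1 lie lower in all 5 knockout libraries, and Gzf1 overlaps between genotypes.

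Hectd3 and Cd320 passed the threshold in each of the 9 fits that left out 1 library. Dnajb12 passed in 0 of these 9 fits (adjusted p = 0.057 to 0.30) and Rbmxl1 in 2 of them, those without knockout replicate 3 or knockout replicate 5 (range of adjusted p over the 9 fits 0.0029 to 0.32). The count of 4 genes became 2 without wild-type replicate 1, 3 or 4 or knockout replicate 1 or 2. At an unadjusted p under 0.05 there were 293 genes, against 632 that chance alone would give. DESeq2 called 7 genes and limma voom with library weights 7, in both cases with the 4 above and Slc10a7 among them (log2 fold change -1.21, SE 0.20, adjusted p = 0.056 in edgeR), a gene named after its values were seen. Without the low-count filter edgeR called 35 genes, 9 higher and 26 lower.

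Among genes of the Dlk1-Dio3 cluster, which is expressed by parental origin from chromosome 12, noncoding RNAs of the maternal copy were lower in the knockout libraries. Meg3 (109541001 to 109571726) was at 156 ± 79.3 CPM (SD, n = 4) in wild-type and 32.6 ± 18.7 CPM (SD, n = 5) in knockout libraries, a log2 fold change of -2.31 (SE 0.48). Mirg (109729764 to 109749460), host of a microRNA cluster, was at 23.7 ± 16.1 and 2.70 ± 2.60 CPM, a log2 fold change of -3.28 (SE 0.61). Dlk1 (109452823 to 109463336), a paternally expressed gene that encodes a Notch ligand homologue, was at 15 ± 10.6 and 8.53 ± 3.90 CPM, a log2 fold change of -0.85 (SE 0.27). Begain was at 2.16 ± 1.35 and 2.94 ± 2.61 CPM, a log2 fold change of 0.32 (SE 0.53). Adjusted over the list alone 3 of the 4 tested members passed the threshold, all lower, and over all genes tested 0 passed (adjusted p = 0.97 for Meg3, 0.31 for Mirg and 0.9998 for Dlk1 and Begain; unadjusted p = 0.00069, 0.00020, 0.0076 and 0.56). Without the low-count filter edgeR called Meg3 (adjusted p = 1.3e-40), Mirg (4.6e-25) and Rian (7.0e-11) over all genes, and without both replicate 4 libraries it called Mirg (0.033). DESeq2 gave adjusted p = 0.18 for Meg3 and 0.11 for Mirg, and no other fit to both runs called either. DESeq2 without the filter called Rian but neither Meg3 nor Mirg. The counts of Meg3 and Mirg are the same with and without the filter, so their unfiltered values depend on the model. An exact permutation of genotype within runs gave p = 0.033 for each, and the unfiltered values do not measure how firm the change is.

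Every knockout library lay below every wild-type library for Meg3 and Mirg. In run2, Meg3 was at 174 and 117 CPM in wild-type and 35.9 and 52.5 CPM in knockout libraries (log2 fold change -1.73, SE 0.66). In run1 it was at 257 and 73.7 CPM in wild-type and 17.1, 47.6 and 9.67 CPM in knockout libraries (-2.76, SE 0.58). Mirg had a log2 fold change of -2.84 (SE 1.01) in run2 and -3.49 (SE 0.76) in run1. Dlk1 had -0.19 (SE 0.45) in run2 and -1.16 (SE 0.32) in run1, and the difference between runs had an unadjusted p of 0.11. Rian, another maternally expressed noncoding RNA of the cluster, was removed by the low-count filter and is named after its values were seen. Its row, merged with a small nucleolar RNA, held 8, 5, 98 and 22 counts in wild-type replicates 1 to 4 and 0, 0, 2, 8 and 1 in knockout replicates 1 to 5. DESeq2 without the filter gave it a log2 fold change of -4.01 (adjusted p = 0.0011). Dio3, at 1.42 ± 0.69 CPM (SD, n = 4) and 1.66 ± 0.50 CPM (SD, n = 5), was near the floor in both genotypes and is likewise named after its values were seen.

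An exact two-sided permutation of genotype within runs (60 arrangements, smallest possible p 0.017) gave p = 0.033 for Meg3 and for Mirg, 0.017 for Rian, and 0.05 for Dlk1 and for Gzf1. Dio3 had 0.67 and Begain 0.85, and over the 7 genes the exact values adjusted to 0.07 for the first 5 and to 0.78 and 0.85 for the others, so that none passed. As a list the Dlk1-Dio3 cluster was lower (camera, adjusted p = 8.5e-11), a call lost with adjusted p = 0.066 under an estimated correlation. Genes flanking the cluster had a median log2 fold change of 0.00 over 12 tested members and a mean of -0.01, although the test pointed up (camera, adjusted p = 0.995), with Yy1 at -0.11 (SE 0.14) and Ppp2r5c at 0.04 (SE 0.15).

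**Figure D3:**
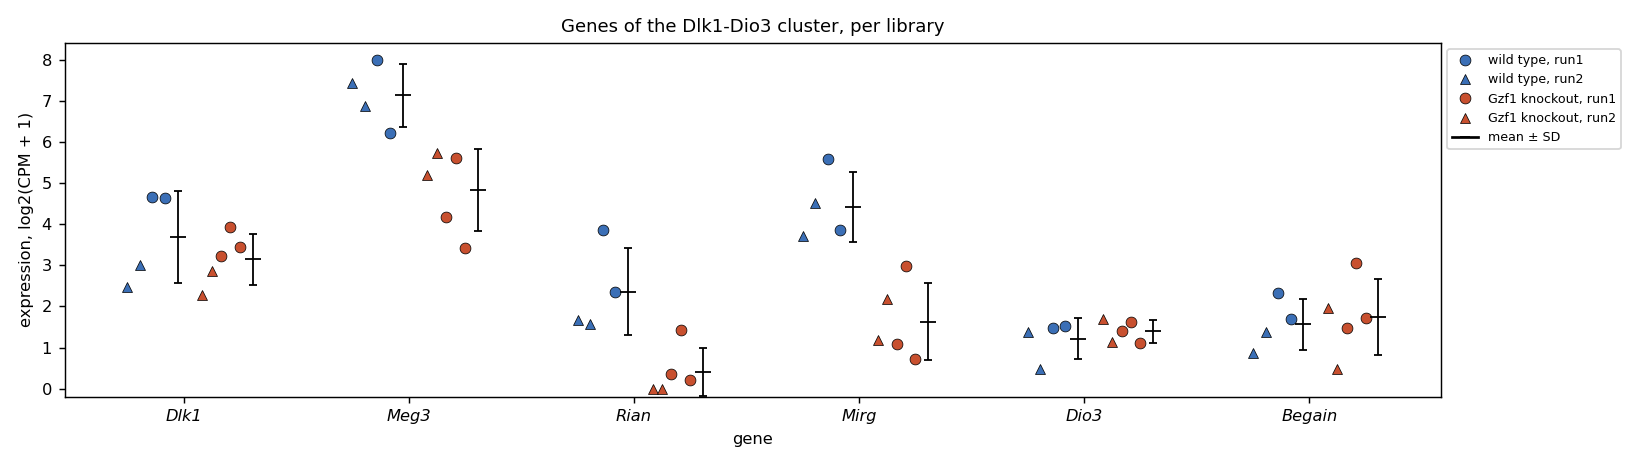
Expression of 6 genes of the Dlk1-Dio3 cluster as log2(CPM + 1) (vertical) for each gene (horizontal). Each point is a library, coloured by genotype and shaped by run, and black marks give mean ± SD of 4 wild-type and 5 knockout libraries. Meg3, Rian and Mirg are lower in all 5 knockout libraries than in any wild-type library, while Dlk1, Dio3 and Begain overlap. For Rian the margin rests on few counts.

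Imprinted genes outside the cluster showed 0 members past the threshold. Of 21 maternally expressed genes 11 had a positive and 10 a negative log2 fold change (camera, adjusted p = 0.86), with H19 at -0.08 (SE 0.15) and Cd81 at -0.04 (SE 0.15). Of 27 paternally expressed genes 13 were positive and 14 negative (adjusted p = 0.69), with Snrpn at 0.00 (SE 0.13) and Peg10 at 0.60 (SE 0.22, unadjusted p = 0.016, adjusted p = 0.9998). Without the low-count filter edgeR called Peg10 too (log2 fold change 0.58, adjusted p = 0.017), while DESeq2 did not (adjusted p = 0.9999). Among 34 factors of DNA methylation and imprint protection 0 passed the threshold (camera, adjusted p = 0.82). Trim28, the corepressor recruited by KRAB zinc finger proteins, had a log2 fold change of 0.06 (SE 0.14), Dnmt3l of 0.19 (SE 0.14) and Zfp57, named after its values were seen, of 0.09 (SE 0.22, adjusted p = 0.9998).

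Of the 21 tested lists 3 passed the threshold with the preset correlation, and with an estimated correlation 0 passed, as with fry. Besides the Dlk1-Dio3 cluster these were immediate early genes and germline genes. Immediate early genes were higher, with 13 of 14 members positive, a median log2 fold change of 0.27 and 0 members past the threshold singly (camera, adjusted p = 0.00010; adjusted p = 0.066 with an estimated correlation). Egr1, a growth factor-induced transcription factor, had 0.55 (SE 0.20) and Junb 0.09 (SE 0.13). The median of the list was 0.38 in run1 and 0.04 in run2. Germline genes silenced by promoter methylation were lower, with 16 of 24 members negative, a median of -0.12 and 0 members past the threshold singly (adjusted p = 0.0045; adjusted p = 0.59 with an estimated correlation). Sohlh2, a germ cell transcription factor, had -0.91 (SE 0.24, adjusted p = 0.9998) and Sycp3, of the synaptonemal complex, -0.05 (SE 0.30). Sohlh2 was called by edgeR without the low-count filter (-0.92, adjusted p = 0.00016) and not by DESeq2 (adjusted p = 0.34). The germline call was lost without wild-type replicate 2 (adjusted p = 0.052) or 4 (adjusted p = 0.64) and without knockout replicate 2 (0.11) or 5 (0.18), and without wild-type replicate 4 the mean log2 fold change was 0.10 rather than -0.15. The count of 3 lists became 7 without wild-type replicate 1 or knockout replicate 1 and 5 without knockout replicate 3, 4 or 5.

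Pluripotency and lineage lists did not pass the threshold in all libraries together. Core pluripotency factors had a median log2 fold change of -0.03 over 18 genes (adjusted p = 0.82), with Sox2 at -0.03 (SE 0.13) and Nanog at -0.33 (SE 0.14, unadjusted p = 0.031, adjusted p = 0.9998). Naive markers had a median of 0.01, a mean of -0.09 and a test pointing down (20 genes, adjusted p = 0.13), with Dppa5a at -0.33 (SE 0.18). Formative and primed markers had a median of 0.20 over 14 genes (adjusted p = 0.053), with Dnmt3a at 0.10 (SE 0.16) and Dnmt3b at -0.05 (SE 0.19). Medians were 0.11 for primitive endoderm (15 genes, adjusted p = 0.15), 0.10 for mesendoderm (13 genes, 0.82), -0.03 for neuroectoderm (14 genes, 0.50) and 0.21 for trophoblast (15 genes, 0.995), here too as adjusted p.

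Fibroblast markers were measured because the stem cells had been grown on feeders. Their median log2 fold change was 0.14 over 25 genes, 20 of them positive (adjusted p = 0.083; adjusted p = 0.94 with an estimated correlation). The mean log2 level of the list was 7.02 and 6.78 in the wild-type and 6.60 and 7.28 in the knockout libraries of run2, and 5.89 and 5.63 in the wild-type and 6.19, 5.93 and 5.63 in the knockout libraries of run1. Col1a1, an abundant fibroblast collagen, had a log2 fold change of 0.16 (SE 0.25). Signalling and metabolic lists did not pass either in all libraries together. Medians were 0.10 for GDNF and Ret signalling with Hoxa10 (8 genes, adjusted p = 0.13), where Etv4 had 0.44 (SE 0.16, adjusted p = 0.9998). They were 0.11 for glycolysis and hypoxia (23 genes, adjusted p = 0.13), 0.04 for p53 targets (23 genes, 0.82), 0.08 for the integrated stress response (22 genes, 0.58), 0.05 for cholesterol synthesis (20 genes, 0.50) and -0.03 for interferon-stimulated genes (12 genes, 0.69).

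**Figure D4:**
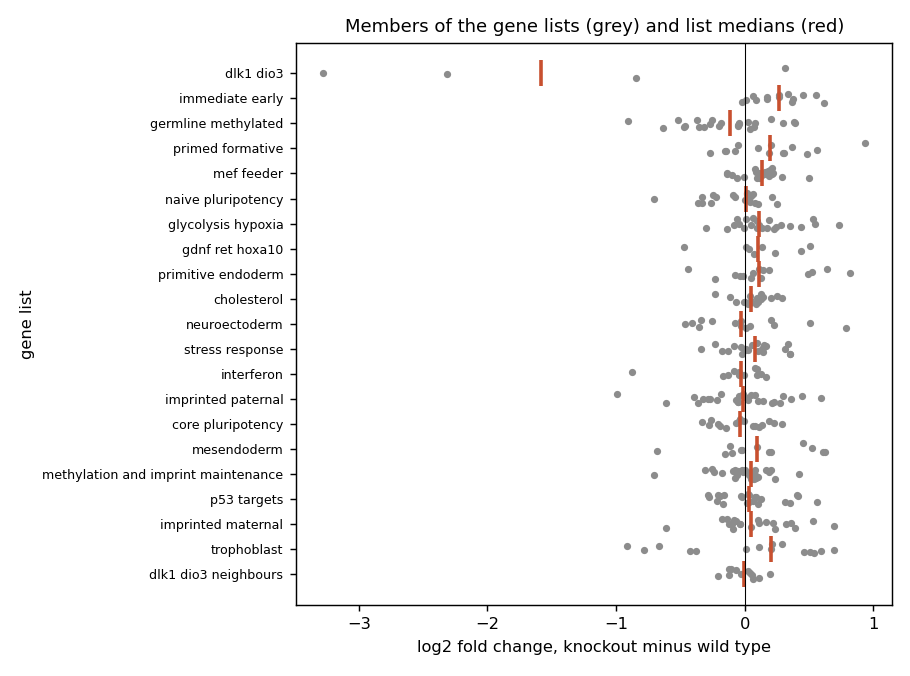
Log2 fold change of knockout against wild type (horizontal) for the tested members of the 21 gene lists (vertical). Each grey point is a gene and each red bar the median of its list. The Dlk1-Dio3 list has its median at -1.58, and the medians of the other lists lie between -0.12 and 0.27.

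Within RGM cells (run2, 2 libraries of each genotype) the contrast called 0 genes at the adjusted threshold in edgeR, with 104 genes at an unadjusted p under 0.05, and DESeq2 called 2. A fit to the 4 RGM libraries alone, which vary less than those of run1, called 9 genes, all lower. They included Hectd3 (log2 fold change -2.45, SE 0.28, adjusted p = 0.00022), Cd320 (-1.37, SE 0.17, adjusted p = 0.00024), Meg3 (-1.76, SE 0.21, adjusted p = 0.0089), Mirg (-2.83, SE 0.45, adjusted p = 0.0091), and Mest, a paternally expressed imprinted gene (-1.70, SE 0.30, adjusted p = 0.022, named after its values were seen). In run1 Mest had -0.11 (SE 0.38), with an unadjusted p of 0.042 for the difference between runs. Gzf1 had -1.63 (SE 0.30, adjusted p = 0.053) in that fit. With all libraries but knockout replicate 4 the contrast called 1 gene. Of the lists, the Dlk1-Dio3 cluster alone passed in the contrast within RGM cells (camera, adjusted p = 0.0011, and 0.50 with an estimated correlation). In the fit to the RGM libraries alone the cluster passed too (camera with the preset correlation, adjusted p = 9.3e-14). There germline genes were lower (adjusted p = 0.0082) and formative and primed markers higher (adjusted p = 0.0096).

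Within run1 (3 knockout and 2 wild-type libraries) 2 genes passed, Hectd3 (adjusted p = 0.028) and Cd320 (adjusted p = 0.042), both lower, with 485 genes at an unadjusted p under 0.05 and 4 calls by DESeq2. Without wild-type replicate 4 both genotypes were V6.5 cells, but only 1 wild-type library was left in run1, and 0 genes passed. Hectd3 then had a log2 fold change of -2.46 (SE 0.38, adjusted p = 0.59) and Cd320 of -1.48 (SE 0.25, adjusted p = 0.59), close to the values with all libraries. The count was also 0 without wild-type replicate 1 or 3 or knockout replicate 1, 2 or 3, was 1 without wild-type replicate 2, and was 8 without knockout replicate 4. Of the lists, 5 passed in the contrast within run1 with the preset correlation and 0 with an estimated one. The Dlk1-Dio3 cluster was lower (camera, adjusted p = 9.5e-09; adjusted p = 0.11 with an estimated correlation) and immediate early genes were higher (1.8e-06; 0.054 estimated). Glycolysis and hypoxia genes (median 0.27, adjusted p = 0.0098, and 0.79 estimated) and primitive endoderm markers (median 0.26, adjusted p = 0.013, and 0.28 estimated) were higher. Naive markers were lower (median -0.10, adjusted p = 0.018, and 0.34 estimated), against a median of 0.03 in run2 (adjusted p = 0.82). In the fit to the run1 libraries alone these 5 lists passed with the preset correlation. There germline genes were also lower (camera, adjusted p = 0.0091) and fibroblast markers higher (adjusted p = 0.027). For the difference of the knockout effect between runs 0 genes passed in edgeR (182 at an unadjusted p under 0.05) and 0 in DESeq2. Across the 12645 genes, which are not independent replicates, the log2 fold changes of the runs had a Pearson r of 0.026 and a Spearman rho of -0.027.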

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

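The levels of the named genes and of the gene lists were searched for libraries far from the rest of their genotype. Of 240 groups examined 9 held such a library, where chance alone, which marks about 1 in 20 groups, would give about 12. Each group pools both runs, and a difference between runs can hide a single odd library. The comparison with chance is therefore rough and does not exclude further such libraries. The value given for each flagged library is the gap to the nearest library divided by the range of the group.

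Knockout replicate 4 stood apart in 5 groups, which are not independent of each other. It was lowest for Hectd3 (gap 0.727, log2(CPM + 1) of 1.81 against a group median of 2.52) and for Msmo1 (gap 0.737, 7.20 against 8.20). It was highest for Trim25 (gap 0.713, 6.79 against 6.28) and for Rian (gap 0.751, 1.42 against 0.22). It was also highest for the Dlk1-Dio3 list (gap 0.725, mean log2 level 3.82 against 2.44), above wild-type replicate 1 at 3.43. Rif1 was highest in wild-type replicate 4 (gap 0.851, 8.36 against 7.65) and Serpinh1 in wild-type replicate 3 (gap 0.912, 8.06 against 7.51). Dio3 was lowest in wild-type replicate 2 (gap 0.866, 0.48 against 1.43), for a gene near the floor. Rab39b had its only knockout count in knockout replicate 3 (gap 1, log2(CPM + 1) of 0.19 against 0).

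The knockout effect of 4 gene lists differed between the runs with a preset correlation, and with an estimated correlation 0 did. Immediate early genes had a median log2 fold change of 0.38 in run1 and 0.04 in run2 (adjusted p of the difference 0.00484; adjusted p = 0.24 with an estimated correlation). Glycolysis and hypoxia genes had 0.27 and -0.02 (adjusted p 0.0102, and 0.94 estimated), and primitive endoderm markers 0.26 and -0.04 (adjusted p 0.0146, and 0.405 estimated). Core pluripotency factors had -0.12 in run1 and 0.13 in run2 (adjusted p 0.0335, and 0.49 estimated). Run1 also differs from run2 in cell line, and 1 of its wild-type libraries is of another line than its knockout libraries.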

How the results depend on the processing

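The alternatives named as added after seeing the data are DESeq2 without the filter, voom with library weights, the exact permutation within runs and the fit without both replicate 4 libraries. The count of 4 changed genes became 2 with a minimum fold change of 1.5, without the run term, with cell line in place of run and without robust estimation. It became 35 without the low-count filter, 7 with DESeq2, 9 with DESeq2 without the filter and 7 with voom. It was 4 with RLE factors and with a minimum count of 30, and 5 at an adjusted p under 0.1. Without both replicate 4 libraries it was also 4, where Mirg and Xlr3a, the latter named after its values were seen, took the place of Dnajb12 and Rbmxl1. With 1 library left out it was 2 to 4, being 2 without wild-type replicate 1, 3 or 4 or knockout replicate 1 or 2. Hectd3 and Cd320 were among the calls in all of these settings. The log2 fold change of Gzf1 passed the threshold without the filter at -1.46 and kept its sign in every setting, from -1.78 to -1.18 with 1 library left out. The number of Dlk1-Dio3 genes passing over the list alone became 0 with the exact permutation, which cannot give less than 0.017 for a gene, and was 2 to 4 in all other settings. The number of gene lists became 0 with an estimated correlation and with fry, 5 without the filter, 5 without both replicate 4 libraries, and 2 to 7 with 1 library left out, reaching 7 without wild-type replicate 1 or knockout replicate 1.

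For RGM cells the count of 0 became 7 without the filter, 2 with DESeq2 and 9 with the RGM libraries alone, and was 0 or 1 with 1 library left out, being 1 without knockout replicate 4. For run1 the count of 2 became 46 without the filter, 4 with DESeq2 and 1 with the run1 libraries alone, where the call was Rab39b, and was 0 to 8 with 1 library left out. The difference between runs gave 1 gene without the filter and 0 in all other settings. The cause of these changes was not tested.

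With a replicate block in place of run the count of genes was 6 (Gzf1 and Slc10a7 in addition to the 4), the log2 fold change of Gzf1 was -1.58 (adjusted p = 0.027) and the count of lists was 5. The labels do not say that the numbers pair the libraries, and the main fit did not use them as pairs. Deviations from the mean of genotype and run had a correlation of -0.07 for replicates 1 and 2, 0.30 for replicate 3 and 0.34 for replicate 4, which joins 2 cell lines. Replicates 1 and 2 share a value by construction, since run2 holds 2 libraries of each genotype. Across knockout libraries, wild-type replicate 2 correlated best with knockout replicate 1. In run1 the log2 levels of same-numbered libraries correlated at 0.973 (replicate 3) and 0.978 (replicate 4). The correlation was 0.962 for wild-type replicate 3 with knockout replicate 4 and for wild-type replicate 4 with knockout replicate 3. A pairing within run1 therefore cannot be excluded. Without removing run the correlations were 0.65 to 0.77, since same-numbered libraries share a run.

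For single genes named in the text 1835 of 1879 values from alternatives left the call as it was, 24 lost a call, 20 gained one and 0 reversed. All but 4 of these genes were uncalled in the main fit, so most values could only stay uncalled or gain a call. Of the 4 called genes, Hectd3 and Cd320 kept the call in 20 of 20 settings, Dnajb12 in 7 and Rbmxl1 in 9. For single lists the figures were 357 of 399, 14, 28 and 0. The sign differed, with the threshold passed in neither fit, in 190 values of genes and 55 of lists. The median log2 fold change of all tested genes was 0.01 with TMM and with RLE factors. Depth limits genes under the floor, which in run2 lay as high as 1.18 CPM.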

Other observations

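The tests on fibroblasts, on left-out libraries, on clones, on a single run and on ribosome synthesis (with its interval) were chosen after the results they bear on were seen, and the tests of other splits, of the neighbours of Meg3 and of pseudogenes were set before. The separate tests of the neighbours of Rbmxl1 and of the other 3 genes and the reassignment of genotype within runs were also chosen after. Rab39b (X chromosome, 75572046 to 75578231, mm10), a small GTPase gene active in neurons, was removed by the low-count filter and is named after its values were seen. It held 13, 4, 76 and 36 counts in wild-type replicates 1 to 4, and 0, 0, 1, 0 and 0 in knockout replicates 1 to 5. Pooled over libraries, the knockout level was 0.0062 of the wild-type level (95% exact interval 0.00016 to 0.035, covering counting error only). DESeq2 without the filter gave a log2 fold change of -6.45 (adjusted p = 1.2e-06), and edgeR on the run1 libraries alone -6.85 (adjusted p = 0.039). Asz1, a germline gene silenced by methylation and also named after its values were seen, held 1, 1, 23 and 33 counts in wild-type and 0, 0, 4, 6 and 1 in knockout libraries, with a log2 fold change of -2.87 in edgeR without the filter (adjusted p = 0.0041) and -2.77 in DESeq2 without the filter (adjusted p = 0.9998).

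Rbmxl1 and Slc10a7 start 448 bp apart on opposite strands of chromosome 8, and both were lower in the knockout (log2 fold change -1.18, SE 0.18, and -1.21, SE 0.20). Urod, named after the call of Hectd3 was seen, starts 904 bp from it on the opposite strand and had a log2 fold change of 0.29 (SE 0.13, adjusted p = 0.9998). Xist was between 0.78 and 8 and Ddx3y between 1.48 and 6.21 CPM of total counts in the 9 libraries. Over the tested genes 31 had every knockout library below every wild-type library and 25 every one above, while chance gives 0.794% of genes in each direction if runs are ignored. When genotype was reassigned within runs, 30 of 60 assignments, the real one included, gave at least 31 genes with such a fall, so the number of separated genes is no evidence of a change.

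Other splits of the 9 libraries into 4 and 5 were fitted in the same way, 100 of the 126 possible. As many genes as the real 4 were called in 3 of the 100, the real one included, a share under 0.05. Of the 53 drawn splits with the real balance of runs, chosen for this count after the result was seen, 1, the real one, called as many and the highest other called 2. The highest other split called 292 genes. It sets wild-type replicates 3 and 4 and knockout replicates 3 and 4 against the rest, so that within run1 knockout replicate 5 stands alone against the others, and the calls point to a structure of the samples, the distance of 1 library. For the count of gene lists 84 of 100 splits, and 43 of the 53, reached the real 3 and the highest other reached 10, so chance cannot be excluded for that count. For the Dlk1-Dio3 list 1 split of the 100, the real one, gave a camera p as small as 4.0e-12. The smallest in another split was 1.8e-08, with knockout replicates 1, 2, 3 and 5 set apart, a grouping close to the real one. Wild-type replicates 2 and 3 with knockout replicates 1 and 4 still gave 2.1e-04, while many splits gave p above 0.05. The splits share libraries and are not independent, and the size of this p cannot be taken at face value.

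Meg3, Mirg and Rian were lower in every knockout library than in any wild-type library. For Rian the margin was within counting error, with 1.67 CPM (8 counts) in knockout replicate 4 and 1.97 CPM (5 counts) in wild-type replicate 2. Fewer feeder fibroblasts are argued against by the fibroblast list, whose median log2 change was 0.139 (SD 0.14). A loss of the whole chromosome region is argued against by 5 tested neighbours within 1 Mb of Meg3, with a median of 0.0396 (SD 0.13). These neighbours lie outside the cluster list, so a smaller deletion inside the cluster was not tested. For Meg3 no single library carried the change, since its log2 change closest to 0 with 1 library left out was -1.67, without wild-type replicate 3. Rian has most of its wild-type counts in that library. Its log2 change was -3.89 and -3.91 without wild-type replicate 1 or 2, and -3.84 and -3.85 without knockout replicate 1 or 2. In the other fits, that without wild-type replicate 3 included, the low-count filter removed Rian, so those were not tested. Silencing of the cluster in single clones, unrelated to the deletion, cannot be told apart, because the log2 gap between the lowest wild-type and the highest knockout level of Meg3 was 0.49 against a range of 1.80 among wild-type libraries. An effect of Gzf1 loss on the maternal RNAs of the cluster stays a hypothesis beside it, which re-expression of Gzf1 or allele-specific methylation in further clones would test.

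Hectd3, Cd320, Dnajb12 and Rbmxl1 fell in knockout libraries of either cell line. A deletion or copy loss around Hectd3, Cd320 and Dnajb12 is argued against by 65 tested genes within 500 kb, whose median log2 change was 0.0376 (SD 0.21), though a deletion inside a gene or its promoter was not tested. Around Rbmxl1 it cannot be told apart, since 4 neighbours were tested, with a median of 0.165 (SD 0.98) and Slc10a7 the lowest at -1.21. The log2 change closest to 0 among the 4 genes in either run was -1.115, for Rbmxl1 in run1, so each of them was lower in both runs. These genes were called by a fit to both runs, which favours genes that change alike in each. Their values therefore cannot decide whether the knockout has effects in one run only. A direct effect of Gzf1 loss and off-target editing shared by the lines may both account for the pattern, and neither was tested here.

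Ribosomal protein genes differed between the runs in both directions. Of 84 genes with a ribosomal protein symbol, 21 were higher and 7 lower in the wild-type libraries of run2. The log2 differences of the 84 genes ran from -5.46 to 1.58. Over all tested genes 3081 of 12645 differed between the same libraries, 1524 higher and 1557 lower in run2. Changes in both directions are therefore not particular to ribosomal protein genes. The size of the difference and the number of named pseudogenes had a Spearman rho of 0.0208 across genes (permutation p = 0.85). Only pseudogenes named after their parent gene were counted, and 60 of the 84 genes had one. Pseudogenes under other names were missed, so reads shared with processed pseudogenes cannot be excluded. A cell line difference in ribosome synthesis cannot be told apart from other effects of run, since the SD of the log2 differences was 1.08 (bootstrap interval 0.67 to 1.45) against a median of 0.73 in expression-matched sets. The SD lay above 1.06, the upper end of the 95% range of those sets and the bound first set for the test. The lower end of its bootstrap interval, 0.67, did not lie above 1.06, so the excess is within its own uncertainty. In the knockout comparison 0 of these genes passed the threshold, with a median log2 fold change of -0.09 (SD 0.19).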
